A study of Mus musculus with 4 samples.

How the data were processed

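Gene expression was measured by single-cell RNA sequencing of pancreatic islet cells from male mice aged 8 weeks, in 4 libraries with 1 library per group. The groups were mice homozygous for floxed alleles of the DNA demethylation enzymes Tet2 and Tet3 without the Pdx1-Cre transgene (Cre-negative), the same floxed alleles with Pdx1-Cre, which acts in the pancreatic epithelium (Cre-positive), offspring of control mothers (control offspring), and offspring of mothers with hyperglycaemia during pregnancy (IHG offspring). Per the labels' protocols, islets were isolated with collagenase, picked by hand, cultured, dissociated with trypsin and loaded on the SeekOne MM microwell platform, whose barcoded beads tag the 3' end of transcripts with unique molecular identifiers (UMIs). How many mice stood behind each library is not given in the sources used here.

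The deposited matrices hold counts, as whole numbers of UMIs per gene and cell barcode for 32285 genes, not normalized. Cell Ranger, Seurat and the mouse build mm10 are named in the submitters' processing notes, with no version or role. Aligner, gene annotation and barcode filter are not given in the sources used here; the lowest barcode in each matrix held 500 UMIs. Gene coordinates were taken from GENCODE vM21 on GRCm38, the assembly that mm10 names, in which 32158 of the 32285 gene identifiers were found. Whether counting used the strand is not given, so overlapping and antisense genes could share reads, and near-identical paralogs such as Hspa1a and Hspa1b, or members of the H2 and Serpina1 families, could split them.

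The matrices held 6421 barcodes and 52489846 UMIs in the Cre-negative library, 10145 and 84146592 in the Cre-positive library, 16459 and 109110492 in the control offspring library, and 12684 and 95818236 in the IHG offspring library. Cells with 500 or more genes and at most 20% mitochondrially encoded UMIs were kept, which left 5928, 9587, 15752 and 11938 cells in that order. Doublets were marked per library with Scrublet as run by scanpy 1.11.5 at an expected rate of 0.06. Its automatic threshold marked 0.152% of Cre-negative and 0% of control offspring cells and was taken to have failed there, so the top 6% of scores were removed in these libraries (6.26% and 6.53% of cells, ties included). The automatic threshold removed 1.71% of Cre-positive and 4.54% of IHG offspring cells. The unequal treatment leaves more doublets possible in the Cre-positive library. After this step 5557, 9423, 14723 and 11396 cells remained, 41099 in all.

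Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries and combined, and 30 principal components with 15 neighbours per cell gave a shared-neighbour graph of all libraries, clustered by Leiden at resolution 1 without batch correction (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9). Each cluster was scored on 15 marker lists fixed before the data were examined, as the mean log2 of its CPM over a typical cluster's CPM with 5 added to each. A cluster took the name of the highest-scoring class where the score was 1 or more and led the next class by 1 or more, where 3 or more markers reached 20 CPM, and where its 10 leading genes by fold did not hold more markers of another class. A cluster whose cells held under 1/3 of their library's median UMIs needed a marker of its class among those 10 genes, and a cluster led by 3 or more cell cycle markers was called proliferating. The typical profile was the median over the main clusters for every clustering. This rule, its thresholds and the fixed profile were settled after clusters had been seen, with several versions tried. Clusters left unnamed held 0.504% of Cre-negative, 15.8% of Cre-positive, 7.17% of control offspring and 3.93% of IHG offspring cells.

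Cells are not replicates and each group had 1 library, so no test between groups was possible and no p-value, standard error or call of a changed gene is given. UMIs were summed per library and class, and counts per 1000000 (CPM) of all gene UMIs in that class were compared as ratios. The 95% intervals of ratios are exact conditional binomial (Clopper-Pearson) intervals, and those of shares of cells are exact binomial intervals. They cover counting error only, not differences between animals, dissociations or library preparations. A count of 0 was set to 3 UMIs for a ratio, which is then a bound. Genes with 20 CPM or more in at least 1 of the libraries compared were counted as higher or lower by a fixed rule of size, a ratio of at least 1.5-fold. In the main comparisons beta-like cells held 33550798 UMIs (Cre-negative), 32225499 (Cre-positive), 74693962 (control offspring) and 55967339 (IHG offspring).

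For each of 21 gene lists fixed before the data were examined, members with 10 CPM or more in at least 1 of the libraries compared were used. The median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. The rule for named genes was also fixed beforehand. It takes, in beta-like cells and for each comparison, the 10 highest and 10 lowest ratios among genes past the 20 CPM filter, leaving out markers of other cell classes, hormones, mitochondrially encoded, ribosomal protein, haemoglobin, immunoglobulin, Xist and Y-linked genes and unnamed gene models. It adds up to 4 members of each list with the largest absolute log2 ratio, Tet1, Tet2, Tet3 and the islet hormones always, and up to 10 genes at least 1.5-fold different in the same direction in both comparisons. In alpha- and delta-like cells it takes the 5 highest and 5 lowest. Not every gene that the rule takes is named in the text. Genes named outside this rule, which are Ifit3 and the heat shock and immediate early genes given by class, were chosen after their values were seen.

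Correlations between comparisons were computed across genes, which are not independent replicates. Their counting intervals came from 200 Poisson redraws of the summed counts. Where both comparisons used the Cre-negative library, 100 sets of unchanged libraries were simulated from a common profile to give the value that counting error around the shared library produces, which leaves out any deviation of that library itself. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out.

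The calculation was tested on simulated counts with 200 changed genes per comparison. These counts held Poisson counting error only. The shares of unchanged genes below therefore check the calculation and are not error rates for real libraries. For Cre-positive against Cre-negative (6255 genes), all genes set 2- or 3-fold apart passed the 1.5-fold rule, as did 41.2% of those set 1.5-fold higher, 52.9% of those set 1.5-fold lower and 0% of unchanged genes, and 94.8% of unchanged genes had an interval that held the true ratio. For IHG against control offspring (5434 genes) the same held for genes set 2- or 3-fold apart, with 44.1%, 55.9%, 0% and 95.0% for the others. Of 100 random lists per comparison, 4 and 9 fell outside the central 95% of their random distribution.

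Results were recomputed under 13 other choices fixed before the data were examined. They were no doublet removal, stricter cell limits (1000 genes and 10% mitochondrial UMIs), median-of-ratios size factors, CPM without hormone and mitochondrially encoded genes, the mean of the cells' own CPM, thinned cells, Leiden resolution 0.5 or 2, each library clustered on its own, beta-like cells with over 1% of UMIs from Gcg, Sst, Ppy and Pyy left out, CPM minimums of 5 or 100, and no minimum with a pseudocount of 1 CPM. Another 7 were added after seeing the data: the control offspring library as reference for Cre-positive and the Cre-negative library for IHG offspring, beta-like cells of the cluster that both libraries of a comparison share most, beta-like cells without the interferon-led cluster, endothelial-like cells without theirs, alpha- and delta-like cells without those holding over 3% of UMIs from Ins1 and Ins2 (the only limit tried), alpha- and delta-like CPM without hormone and mitochondrially encoded genes, and alpha-, delta- and endothelial-like cells of the cluster shared most where both libraries held 100 cells there, for the interferon and immediate early lists. Lists of Cre-positive against control offspring cells were also computed after seeing the data. The sign rule for list medians was changed for a time to a sign relative to the median of all genes and then set back to the plain sign, which is the rule used here.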

Results

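Single-cell transcriptomes of mouse pancreatic islets were compared along a pair of contrasts. The first asked how islet cells differed when Tet2 and Tet3, enzymes that oxidise 5-methylcytosine, were floxed in the presence of Pdx1-Cre. The second asked how islet cells of adult male offspring differed after exposure to maternal hyperglycaemia, a model in which the study followed glucose tolerance and insulin secretion. Each of the 4 groups was represented by 1 library, with median depths of 7373 UMIs per barcode (Cre-negative), 5809 (Cre-positive), 5334 (control offspring) and 6958 (IHG offspring). No value below has a replicate check, and all intervals are 95% intervals of counting error only.

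Beta-like cells, the insulin-producing class defined by Ins1, Ins2, Iapp and Mafa among other markers, made up 57.6% (56.3 to 58.9) of kept cells in the Cre-negative library and 28.4% (27.5 to 29.4) in the Cre-positive library. Endothelial-like cells made up 3.33% (2.87 to 3.83) and 16.5% (15.8 to 17.3), and macrophage-like cells 1.06% (0.809 to 1.37) and 7.35% (6.84 to 7.90). Alpha-like cells made up 17.1% and 15.4%. Delta-like cells made up 9.47% and 9.23%, but 9.23% and 0.271% with no doublets removed and 9.65% and 0% with each library clustered on its own (unnamed clusters then held 21.9% and 30.5% of Cre-positive cells). Among offspring, beta-like cells made up 70.4% (69.7 to 71.2) in the control and 51.7% (50.8 to 52.6) in the IHG library, while alpha-like cells made up 6.66% (6.27 to 7.08) and 17.0% (16.3 to 17.7) and delta-like cells 7.70% (7.28 to 8.14) and 12.5% (11.9 to 13.1). The delta-like shares were 0.540% and 7.81% with no doublets removed and 5.03% and 4.23% with each library clustered on its own, so not even their order held. Islets were picked by hand and dissociated, and unnamed clusters held 15.8% of Cre-positive against 0.504% of Cre-negative cells, so these shares also carry yield and naming. With each library clustered on its own the beta-like share differed by -11.0 instead of -29.2 percentage points between Cre-positive and Cre-negative, and by -9.49 instead of -18.7 points between IHG and control offspring.

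**Figure D1:**
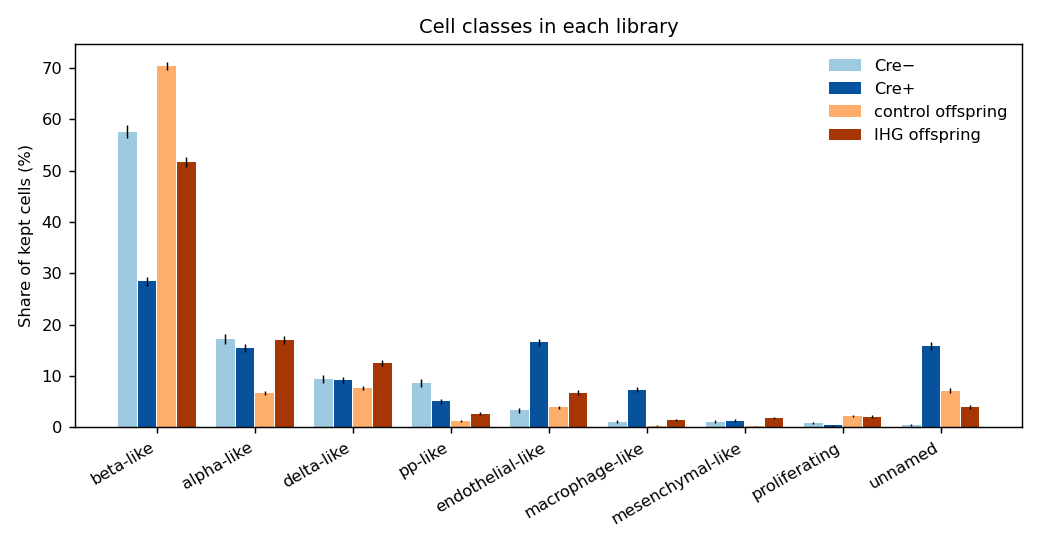
Share of kept cells in each class (%, vertical axis) for the 4 libraries, with exact 95% binomial intervals as error bars that cover counting error only. Beta-like cells ranged from 28.4% in the Cre-positive to 70.4% in the control offspring library.

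Tet2 (chromosome 3, 133463679 to 133545139, GRCm38, minus strand) and Tet3 (chromosome 6, 83362373 to 83459084, minus strand) were both detected in beta-like cells of the Cre-positive library. Tet2 stood at 33.1 CPM against 46.7 CPM in the Cre-negative library, 1.41-fold lower (1.30 to 1.52), and Tet3 at 26.5 against 34.2 CPM, 1.29-fold lower (1.18 to 1.42). Tet1 (chromosome 10, 62804570 to 62908996, minus strand), which was not floxed, was 2.25-fold lower (1.97 to 2.59). After thinning, a Tet2 UMI was found in 6.58% of Cre-positive and 9.14% of Cre-negative beta-like cells (29.3% and 35.0% unthinned), with 112 and 107 shallow cells left out and median depths of 10167 and 9534 UMIs. No class here is known to lack Tet2, so no background share is given. The libraries count 3' tags, which can lie outside floxed exons, so these levels do not check the deletion. In IHG against control offspring beta-like cells, Tet2 was 1.24-fold lower (1.17 to 1.31), Tet3 1.17-fold lower (1.10 to 1.25) and Tet1 1.00-fold lower (0.899 to 1.12).

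In beta-like cells Nupr1, a stress-induced chromatin regulator, was 44.8-fold higher (33.3 to 61.9) in the Cre-positive than in the Cre-negative library, the interferon-induced Oasl2 29.2-fold (19.6 to 45.5), Trib3, a pseudokinase of the integrated stress response, 26.3-fold (19 to 37.6), and the AP-1 member Fosl2 14.7-fold (12.1 to 18.0). Bag3, a co-chaperone of the heat shock response, was 12.9-fold higher, Chac1, a glutathione-degrading enzyme, 11.8-fold, Atf3 11.4-fold, Phgdh, the first enzyme of serine synthesis, 9.19-fold, the adenosine receptor gene Adora2b 8.43-fold and Plk3 7.78-fold. Among the lowest ratios were those of Zfp423 at 414-fold lower (114 to 3428, from 2 against 863 UMIs), Moxd1 at 209-fold, Cldn2 at 30.0-fold, Mc5r at 27.9-fold and Sema3c at 25.3-fold lower. The imprinted gene Dlk1 (chromosome 12, 109452823 to 109463336) was 24-fold lower (21.3 to 27.2), Prss23 17.0-fold, Basp1 15.7-fold and Dclk1 12.7-fold lower. Within cluster 0, which both libraries share most, Prss23, Basp1 and Dclk1 were not lower, on 13, 12 and 14 UMIs in both libraries together. That cluster held only 178 Cre-negative and 334 Cre-positive cells, 5.56% and 12.5% of the class.

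Among 6456 genes, 445 were at least 1.5-fold higher and 1285 at least 1.5-fold lower. The median of all ratios was -0.22 on the log2 scale; with median-of-ratios scaling it was -0.02 and the counts were 709 higher and 673 lower, so 51.3% rather than 25.7% of genes past the rule were higher. Different clusters held most of the class, cluster 3 with 86.8% of Cre-negative and cluster 2 with 75.7% of Cre-positive beta-like cells. Against control offspring beta-like cells, 365 genes were higher and 124 lower in Cre-positive cells, of which 182 and 54 were also higher and lower against Cre-negative cells, while 28 of the 365 were lower and 6 of the 124 higher there.

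The immediate early and heat shock list had the highest median of the 21 lists in this comparison. Of its 35 measured members 20 were higher and 1 lower, with a median of 0.80 (log2), above all 10000 random lists. Hsph1 was 6.17-fold and Dnaja1 3.72-fold higher. The median of this list was 1.06 in delta-like, 0.21 in endothelial-like and -0.36 in alpha-like cells, where that of all genes was -0.47. In the interferon and antigen presentation list 11 of 22 members were higher and 0 lower (median 0.61, above all random lists), among them Irf7, the interferon regulator, at 7.61-fold (5.63 to 10.5), the antiviral tether Bst2 at 5.47-fold and Ifit1 at 5.37-fold. Of 35 unfolded protein response genes 14 were higher and 1 lower (median 0.46, above all random lists), with Herpud1 of endoplasmic reticulum degradation 3.69-fold and the transcription factor Cebpb 3.03-fold higher. Ribosomal protein genes had 13 of 63 members higher and 0 lower (median 0.22, above all random lists), led by Rpl8 at 3.38-fold and Rpl28 at 3.28-fold. Against control offspring cells the medians of these 4 lists were 0.70, 0.66, 0.34 and 0.30, again above all random lists. Within cluster 0 those of the immediate early, interferon and unfolded protein response lists were 0.47, 0.60 and 0.20.

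Genes normally kept low in beta cells had 7 of 10 measured members lower and 1 higher in Cre-positive than in Cre-negative cells, with a median of -1.35 below all random lists. Fev, a transcription factor of endocrine progenitors, was 10.2-fold lower (7.47 to 14.3), the fatty acid carrier gene Fabp5 3.61-fold and the surface marker Cd81 3.53-fold lower. In cluster 0 this median was 0.15, where Fev and Fabp5 were not lower on 7 and 14 UMIs in both libraries together, and control offspring cells lay -1.84 from Cre-negative cells on the same list. The TET and DNA methylation list had 5 of 22 members lower and 2 higher (median -0.47, percentile 0.910), with the O-GlcNAc transferase Ogt 2.27-fold and Idh1 2.13-fold lower and Mbd3 2.17-fold higher; the control offspring median was -0.45. Nuclear oxidative phosphorylation genes had 5 of 76 members higher and 1 lower (median 0.01, percentile 99.8), a median that turned to -0.03 in thinned cells.

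Genes of beta-cell function lay both ways. In the transcription factor and identity list 1 of 25 members was higher and 3 were lower (median 0.03, percentile 92.6): the maturity marker Ucn3 (chromosome 13, 3940688 to 3945349) was 3.40-fold higher (3.30 to 3.51), while the glucose transporter gene Slc2a2 (chromosome 3, 28697903 to 28731359) was 2.27-fold (2.21 to 2.32), Rfx6 1.70-fold and Ldb1 1.58-fold lower. In the incretin, receptor and cAMP list 11 of 38 members were lower and 4 higher (median -0.35, percentile 2.86), with Glp1r, the GLP-1 receptor gene, 2.01-fold lower (1.96 to 2.06), Rgs2 2.26-fold lower and the fatty acid receptor gene Ffar1 1.97-fold higher. Control offspring differed from Cre-negative cells by 1.17-fold for Slc2a2 and 1.07-fold for Glp1r, and by 5.75-fold for Ucn3. Ins1 (chromosome 19, 52264297 to 52265476) was 1.38-fold and Ins2 1.08-fold higher. The glucose sensing and excitability list had 9 of 30 members lower and 3 higher (median -0.23, percentile 29.3), with the sodium channel gene Scn3a 3.74-fold lower and the cation channel gene Trpm5 2.5-fold higher.

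The medians of the other lists lay within the central 95% of random lists. Calcium handling had 9 of 35 members lower and 1 higher (median -0.31), including the calcium buffer Calb1 at 5.65-fold and the calcium release channel gene Itpr1 at 5.59-fold lower. The PI3K, insulin and IGF list had 11 of 36 lower and 3 higher (median -0.26), with Ddit4 5.76-fold lower and Irs2 3.08-fold higher. Exocytosis had 4 of 34 lower and 2 higher (median -0.28), proinsulin processing 5 of 27 lower and 1 higher (median -0.28), glycolysis and TCA cycle 7 of 31 lower and 2 higher (median -0.19), and lipid metabolism 6 of 30 lower and 2 higher (median -0.28). Antioxidant genes had 6 of 29 higher and 4 lower (median -0.07), with the metallothionein genes Mt1 and Mt2 7.17-fold and 6.75-fold higher. Cell cycle genes had 1 of 14 higher and 1 lower (median -0.06), imprinted genes 2 of 31 higher and 5 lower (median -0.11), serotonin and prolactin response genes 1 of 11 higher and 2 lower (median -0.08), and mitochondrially encoded transcripts 0 of 13 higher and 1 lower (median -0.14).

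Hormone transcripts of other endocrine classes in beta-like cells also differed. Sst was 4.96-fold lower and Gcg 7.09-fold higher in the Cre-positive library, and 11.4% of Cre-negative and 6.35% of Cre-positive beta-like cells had over 1% of their UMIs from Gcg, Sst, Ppy and Pyy. Without those cells Sst was 0.02 (log2) higher rather than lower. Gcg also stood at 3027 CPM in Cre-positive against 338 CPM in Cre-negative endothelial-like cells, which do not make it.

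**Figure D2:**
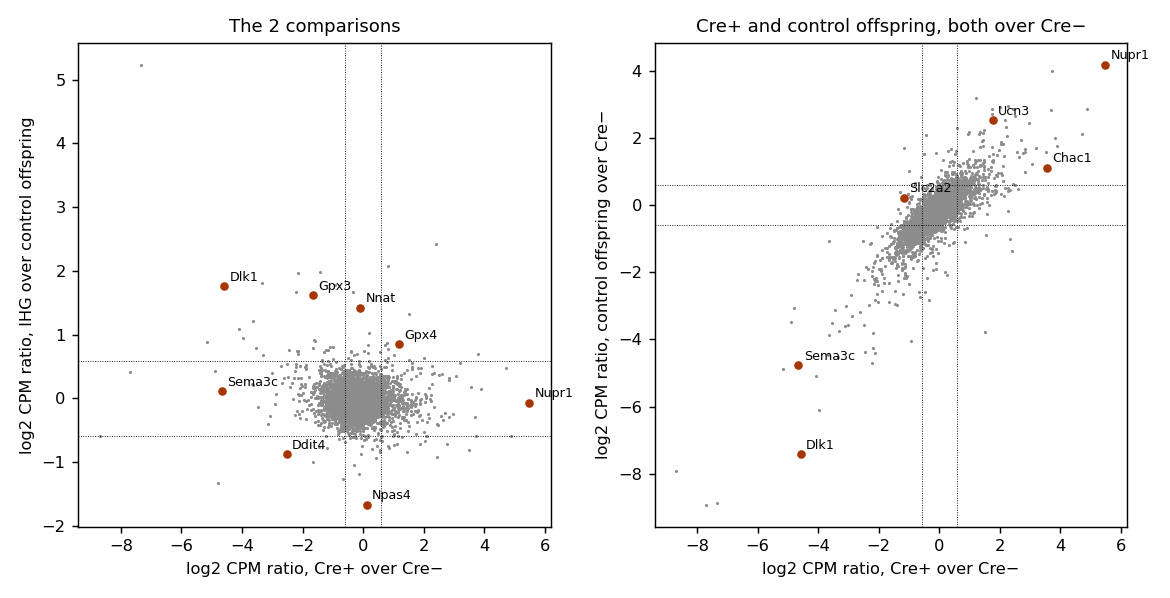
Each point is 1 gene in beta-like cells, with log2 CPM ratios on both axes and dotted lines at 1.5-fold. On the left, IHG over control offspring is set against Cre-positive over Cre-negative, with a Pearson correlation of -0.112 across 6535 genes. On the right, control offspring over Cre-negative is set against Cre-positive over Cre-negative, with a correlation of 0.834 across 6275 genes. Unchanged libraries simulated with counting error alone gave 0.58 because they share a library, which is not a part of the 0.834. The covariances were 0.291 and, simulated, 0.0016.

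Beta-like cells of IHG offspring lay close to those of control offspring, with 71 genes past the 1.5-fold rule. The antioxidant selenoenzyme gene Gpx3 was 3.06-fold higher (2.83 to 3.31), the imprinted gene Nnat, neuronatin, 2.68-fold (2.60 to 2.76), Th, tyrosine hydroxylase of catecholamine synthesis, 2.04-fold (1.96 to 2.12), Kl 1.86-fold and Msln 1.82-fold higher. Gpx4, Pcsk1n, an inhibitor of prohormone convertase 1, Ptov1, the receptor tyrosine kinase gene Ret and Dusp26 were 1.80-, 1.79-, 1.78-, 1.75- and 1.74-fold higher. The activity-induced transcription factor gene Npas4 (chromosome 19, 4984355 to 4990316) was 3.18-fold lower (3.08 to 3.29), Tcim 2.41-fold, the lipoprotein lipase gene Lpl 2.28-fold, Snhg11 1.91-fold and Ddit4 1.84-fold lower. Kcnq1ot1 and Zim1, both imprinted, were 1.83-fold and 1.80-fold lower, followed by Fabp3, Gem and Atf3 at 1.79-, 1.76- and 1.75-fold lower; Msln, Ret and Atf3 took the opposite sign within cluster 0, which both libraries share most.

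Among 5522 genes, 32 were at least 1.5-fold higher and 39 at least 1.5-fold lower. The counts were 44 higher and 24 lower with median-of-ratios scaling (64.7% rather than 45.1% higher) and 70 and 42 without hormone and mitochondrially encoded genes (62.5% higher). Cluster 5 held 41.6% and cluster 0 28.5% of IHG beta-like cells, while clusters 0 and 1 held 38.4% and 37.6% of those of control offspring; within cluster 0 there were 62 genes higher and 36 lower, of which 14 and 11 were past the rule in the same direction in the whole class.

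Immediate early and heat shock genes were the list farthest from its random lists in this comparison. Of 34 measured members 8 were lower and 0 higher (median -0.30, below all random lists), with the AP-1 member Fosb 1.64-fold and the shear-responsive factor gene Klf2 1.73-fold lower; the median was 0.02 with each library clustered on its own and 0.39 within cluster 0, where Fosb was also not lower. The TET and DNA methylation list had 1 of 21 members lower (Gadd45b, 1.54-fold, 1.40 to 1.70) and 0 higher, with a median of -0.15 at percentile 1.26. Glucose sensing genes had 0 of 29 members past the rule and a median of 0.02 at percentile 97.8, nuclear oxidative phosphorylation genes 0 of 76 and -0.01 at percentile 98.3, and both medians changed sign under at least 1 other scaling. The remaining medians lay within the central 95% of random lists.

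Within those remaining lists single members stood out. Mafa (chromosome 15, 75745490 to 75748228), a transcription factor of mature beta cells, was 1.57-fold lower (1.55 to 1.59) at 814 against 1279 CPM and was the 1 of 25 identity genes past the rule (median -0.08). Imprinted genes had 1 of 30 higher and 4 lower (median -0.08), the PI3K and IGF list 0 of 35 higher and 3 lower (median -0.04; Igfbp5 1.91-fold lower), antioxidant genes 2 of 29 higher and 2 lower (median 0.01; Mt2 1.65-fold lower), and genes kept low in beta cells 1 of 7 higher and 3 lower (median -0.03). The unfolded protein response had 1 of 34 lower (Ppp1r15a, 1.59-fold; median -0.11), interferon genes 1 of 17 (Rsad2, 1.77-fold; median -0.11), exocytosis 1 of 32 (Exph5, 1.54-fold; median -0.04), incretin and cAMP genes 1 of 37 (Rgs4, 1.67-fold, not lower in cluster 0; median -0.08), serotonin and prolactin response genes 1 of 10 (Socs3, 1.64-fold; median -0.14) and mitochondrially encoded transcripts 1 of 12 (mt-Atp8, 1.52-fold; median -0.07). Proinsulin processing had 1 of 27 higher (Pcsk1n; median -0.04) and lipid metabolism 1 of 29 (Fasn, 1.67-fold, not higher in cluster 0; median -0.11). Calcium handling (33 members, median -0.01), glycolysis and TCA cycle (30, -0.01), cell cycle (14, -0.03) and ribosomal protein genes (63, -0.08) had 0 members past the rule. Ins1 was 1.14-fold and Ins2 1.06-fold higher, and Ppy, the pancreatic polypeptide gene of another endocrine class, was 4.23-fold higher (4.10 to 4.36), though it also stood at 223 against 67.9 CPM in endothelial-like cells, which do not make it.

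**Figure D3:**
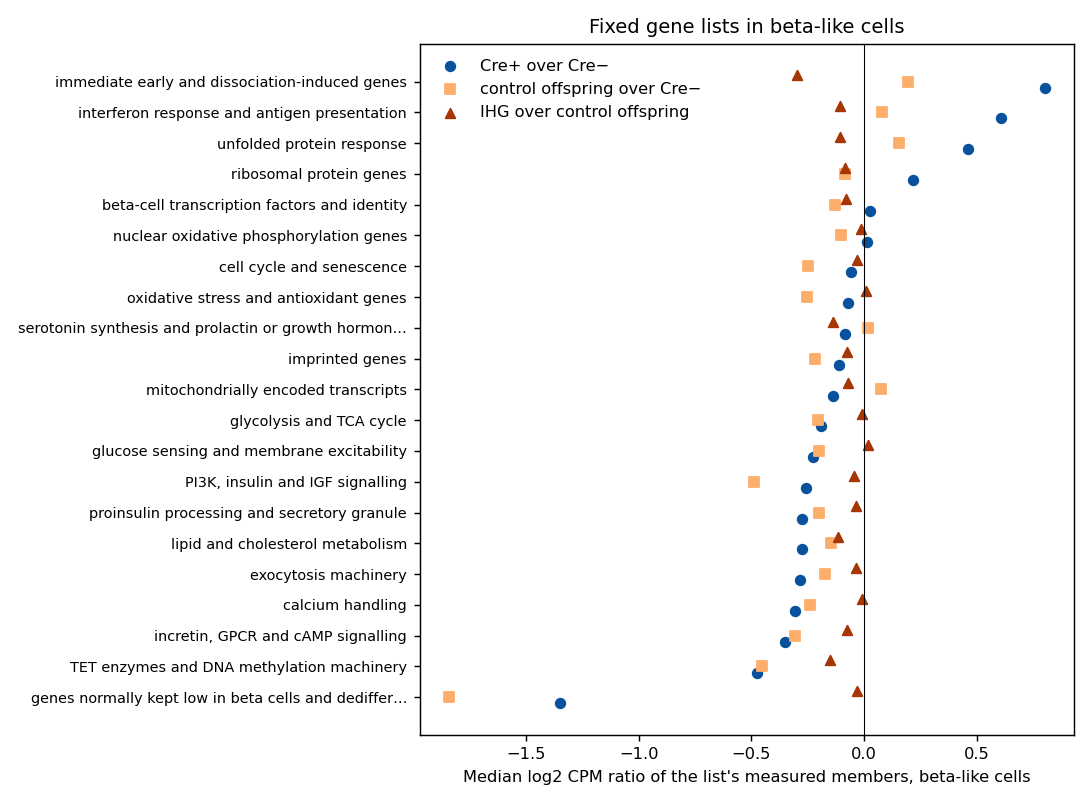
Median log2 CPM ratio of the measured members of each of the 21 fixed gene lists in beta-like cells, for Cre-positive over Cre-negative (circles), control offspring over Cre-negative (squares) and IHG over control offspring (triangles). The immediate early list lay at 0.80, 0.20 and -0.30, and the list of genes kept low in beta cells at -1.35, -1.84 and -0.03.

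Both comparisons were set side by side to ask whether genes that differed with Cre also differed after intrauterine hyperglycaemia. Ddit4, a stress-induced inhibitor of mTOR signalling, was lower in both (5.76-fold and 1.84-fold), as were Tcim, Nfkbiz and Dusp1, while Gpx4 (2.28-fold and 1.80-fold), Msln, Cdc34, Ptov1, Ninj1 and Anpep were higher in both. Within the cluster shared most, Msln was lower in both, Anpep was lower with Cre and Dusp1 was not lower after hyperglycaemia. Across 6535 genes with 20 CPM or more in at least 1 library, 13 genes were higher in both where independent lists would share 4.01, and 10 were lower in both where they would share 10.1. Opposite directions were met by 17 genes higher with Cre and lower with IHG (3.59 for independent lists) and by 29 the other way (11.3). Pearson's r was -0.112 (-0.133 to -0.083) and Spearman's rho 0.003 across genes, and r turned positive, to 0.038 at Leiden resolution 2, 0.083 with each library clustered on its own and 0.294 within shared clusters.

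The reference libraries themselves lay far apart. In beta-like cells of control offspring against Cre-negative mice, 234 genes were higher and 1236 lower, with a median absolute log2 ratio of 0.34; this was 0.35 for Cre-positive against Cre-negative, 0.19 for control offspring against Cre-positive and 0.13 for IHG against control offspring. Of the genes past the rule for Cre-positive against Cre-negative, 149 were also higher and 857 also lower in control offspring against the same Cre-negative library, where independent lists would share 11.9 and 253 and libraries simulated with counting error alone shared 0. The covariance of these ratios was 0.291, against 0.0016 from the counting error of the shared library. The simulated values leave out any deviation of the Cre-negative library itself, from which part or all of the excess may come. Moxd1, Zfp423, Dlk1 and Prss23 were all lower in control offspring too, and Nupr1 was 18.1-fold and Bag3 7.17-fold higher.

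The summed interferon list was higher in Cre-positive than in Cre-negative cells of each class examined. Its median was 0.66 in alpha-like cells (12 of 21 members higher), 0.88 in delta-like cells (15 of 25), 0.85 in endothelial-like cells (21 of 34), 1.25 in macrophage-like cells (25 of 36) and 0.91 in mesenchymal-like cells (23 of 33). In endothelial-like cells Ifit1 was 8.56-fold (5.16 to 15.4), Irf7 5.59-fold (3.74 to 8.77) and Ifit3 5.35-fold (3.68 to 8.08) higher. B2m and H2-D1 of antigen presentation were lower there, with ratios of 0.858 (0.809 to 0.911) and 0.887 (0.841 to 0.937). Cluster 15 held 90.8% of Cre-negative endothelial-like cells, while cluster 7 held 75.4% and the interferon-led cluster 19 held 23.2% of Cre-positive ones. Without cluster 19, which these same genes lead, the endothelial-like interferon median was -0.48 rather than 0.85. The macrophage- and mesenchymal-like classes held only 59 and 58 Cre-negative cells. Genes past the rule in beta-like cells lay the same way in endothelial-like cells, with medians of 0.71 over 327 higher and -0.51 over 835 lower genes, against -0.27 for all genes. Genes with a higher level in beta-like cells were kept here. Ins2 stood at 5094 CPM in Cre-positive and 2867 CPM in Cre-negative endothelial-like cells, so free RNA may give part of this.

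For IHG against control offspring, the summed immediate early and heat shock list was lower in all of these classes. Its median was -1.23 in alpha-like cells (34 of 36 members lower), -1.0 in delta-like cells (28 of 35), -0.84 in endothelial-like cells (24 of 35), -0.83 in macrophage-like cells (25 of 35) and -0.78 in mesenchymal-like cells (25 of 35). Clusters differed here too: cluster 7 held 95.8% of control and 33.7% of IHG endothelial-like cells, cluster 15 3.47% and 66.1%. Within the cluster of each class that both libraries share most (4, 6 and 7) the median was -0.47 in alpha-like, 0.07 in delta-like and -0.31 in endothelial-like cells. In alpha-like cells Hspa1b, an inducible heat shock protein gene, stood at 3898 against 11552 CPM and Fos at 1476 against 3147 CPM. Cre-negative and Cre-positive alpha-like cells stood at 3930 and 7992.5 CPM for Hspa1b and at 3281 and 702 CPM for Fos. The Cre-negative library thus lay near IHG offspring for Hspa1b but near control offspring for Fos. Which offspring library was the unusual one cannot be told from these levels. The control offspring library held 49 macrophage-like and 30 mesenchymal-like cells.

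In alpha-like cells, the glucagon-producing class, of the Cre-positive against the Cre-negative library Slc5a3, a myo-inositol transporter gene of osmotic stress, was 15.7-fold higher (11.4 to 22.1), Bag3 14.6-fold and Eppk1 9.90-fold, and Ppp2r2c 16.5-fold, the GABA receptor subunit gene Gabrg1 16.1-fold and the antitrypsin gene Serpina1a 14.1-fold lower. Control offspring differed from Cre-negative cells the same way, with Slc5a3 8.97-fold, Bag3 18.4-fold and Eppk1 9.50-fold higher and Ppp2r2c 21.3-fold, Gabrg1 16.7-fold and Serpina1a 365-fold lower. The Serpina1a value rested on 1 control offspring against 484 Cre-negative UMIs (65.3 to 14461). Of 6774 genes 310 were higher and 2618 lower around a median of all genes of -0.47 (299 and 2451 for control offspring against Cre-negative), and glycolysis and TCA cycle genes had 19 of 32 members lower (median -0.69, percentile 0.240). Gcg took 112110 CPM of Cre-negative and 290060 CPM of Cre-positive alpha-like UMIs, and without hormone and mitochondrially encoded genes 762 were higher and 975 lower, with a glycolysis median of -0.36. After thinning, a Gcg UMI was found in 83.5% of Cre-negative and 100% of Cre-positive alpha-like cells. Cluster 11, with most of the Cre-negative cells, scored 3.55 for alpha, and cluster 4, with most of the Cre-positive cells, 3.08. Whether cells without Gcg shaped the ratios was not tested. In IHG against control offspring Gpx4 was 3.05-fold higher (2.30 to 4.12) and Pgls of the pentose phosphate pathway 2.11-fold, while the immediate early gene Egr4 was 14.8-fold (11.0 to 20.2), Ccn1 9.65-fold, the prolactin receptor gene Prlr 7.14-fold and Glp1r 6.89-fold lower. Of 5802 genes 77 were higher and 417 lower (323 and 343 without hormone and mitochondrially encoded genes); nuclear oxidative phosphorylation genes had a median of 0.22 above all random lists, and the beta-cell transcription factor and identity list had 6 of 24 members lower (median -0.37, below all random lists). Cluster 11 held 82.7% of Cre-negative and cluster 4 96.6% of Cre-positive and 96.8% of control offspring alpha-like cells, against 43.9% of IHG ones, and Ins2 stood at 14414 CPM in control and 2146 CPM in IHG offspring. Without alpha-like cells holding over 3% insulin UMIs the identity median was -0.36, and Prlr and Glp1r were each 2.10 (log2) lower rather than 2.84 and 2.79.

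Delta-like cells, the somatostatin-producing class, had Ppp1r17, a phosphatase inhibitor gene, 169-fold higher (30.1 to 6694, from 319 against 1 UMI), Adh1 82.1-fold, Mt2 51.0-fold and Bag3 35.5-fold higher in the Cre-positive library, with Mdga2 31.2-fold, Cpne7 23.7-fold and Myof 13.7-fold lower. Control offspring differed from Cre-negative cells the same way, with Ppp1r17 137-fold, Adh1 69.2-fold, Mt2 31.9-fold and Bag3 23.7-fold higher and Mdga2 40.3-fold, Cpne7 12.0-fold and Myof 13.6-fold lower. In these ratios Adh1 rested on 2 and Ppp1r17 on 1 Cre-negative UMI, with an Adh1 interval of 22.5 to 681 for Cre-positive. Of 6928 genes 599 were higher and 1167 lower (656 and 1753 without hormone and mitochondrially encoded genes; 472 and 1233 for control offspring against Cre-negative). Cluster 8 held 94.5% of Cre-negative and cluster 6 97.6% of Cre-positive delta-like cells, and Ins2 stood at 8945 and 53706 CPM. Without cells holding over 3% insulin UMIs, 21.6% of the class in the Cre-positive library, Adh1 and Mt2 were 4.29 and 3.13 (log2) higher rather than 6.36 and 5.67. In IHG against control offspring Dlk1 was 4.43-fold higher (3.9 to 5.05), Mapk4 3.25-fold and Ly6h 3.12-fold higher, and Cib3 6.79-fold, Mt2 5.50-fold and the synaptotagmin-like gene Sytl4 4.93-fold lower. Of 6345 genes 257 were higher and 360 lower (537 and 374 without hormone and mitochondrially encoded genes), and unfolded protein response genes had 9 of 32 members lower (median -0.33, below all random lists). Ins2 stood at 99761 CPM in control and 23786 CPM in IHG offspring, and cluster 6 held 94.3% and 35.2% of the class. Without cells over 3% insulin UMIs, 44.5% of the control class, 154 genes were higher and 696 lower, the unfolded protein response median was -0.19, Dlk1 was 1.78 (log2) higher rather than 2.15, Mapk4 and Ly6h were each 0.83 higher rather than 1.70 and 1.64, and Cib3 and Mt2 were 1.66 and 0.54 lower rather than 2.76 and 2.46.

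**Figure D4:**
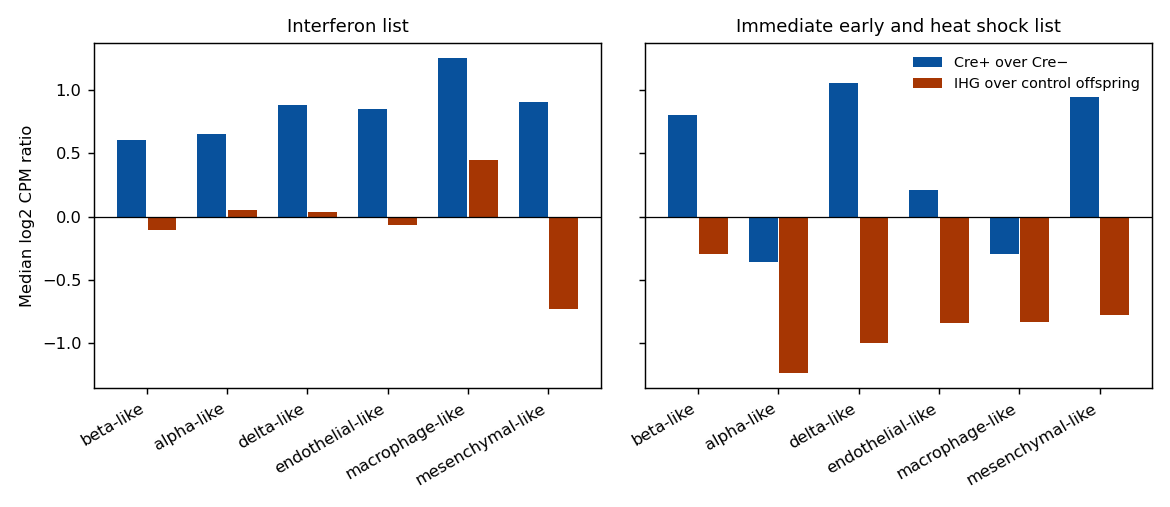
Median log2 CPM ratio (vertical axis) of the interferon list (left) and the immediate early and heat shock list (right) in 6 cell classes, for Cre-positive over Cre-negative and IHG over control offspring. The interferon medians for Cre-positive over Cre-negative ran from 0.61 to 1.25, and the immediate early medians for IHG over control offspring from -0.30 to -1.23.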

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

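The tests on endothelial-like cells for the interferon genes and for the Cre-negative library, and those on beta-like cells alone and on handling for the immediate early genes, were chosen after their results had been seen. All 3 patterns weighed here were also found in these data.

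Cells in 6 unnamed clusters were flagged because no comparison used them and their largest count from a single library was 51 or more. Another unnamed cluster, with at most 8 cells of any library, was not flagged. An alpha and delta mixture with Gcg, Sst and Hhex held 724 Cre-positive, 285 control offspring, 25 IHG offspring and 0 Cre-negative cells at a median of 12700.5 UMIs. A mixture of endothelial and mural markers, led by Rgs5, Notch3 and Acta2, scored 6.78 for endothelial and 4.34 for mesenchymal. It held 574 control offspring cells and 130 Cre-positive, 46 IHG offspring and 2 Cre-negative ones. A mixture of Ppy and beta-cell markers held 499 Cre-positive cells and 156 control offspring, 91 IHG offspring and 2 Cre-negative ones. Cells with Hbb-bs, Mgp and Acta2 held 279 IHG offspring cells and 36, 17 and 6 of control offspring, Cre-positive and Cre-negative. Venous endothelial-like cells with Selp, Ackr1 and Vwf held 51 Cre-positive and 13 Cre-negative cells. Neuron-like cells with Vip, Npy and Prph held 58 Cre-positive cells, 2 of IHG offspring and 1 Cre-negative.

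Interferon genes, summed by class, were higher in the Cre-positive library in all 6 classes examined, and 26 of 34 measured genes were highest there among the 4 libraries in endothelial-like cells. The tables argue against the deletion acting inside Pdx1-lineage cells alone, since the median in endothelial-like cells was 0.848; whether cluster 19 alone gave this cannot be told apart, because the cluster (23.2% of Cre-positive and 0% of Cre-negative endothelial-like cells) is led by these same genes and leaving it out (-0.477) takes the interferon-high cells from 1 library only. They argue against free RNA from macrophage-like cells, since the excess in beta-like cells (486 CPM) was 96.6 times what those cells would bring with their markers, and, in beta-like cells, against their own interferon-led cluster alone, which held 9.0% of Cre-positive cells but without which the median was 0.60 rather than 0.61. An infection, a litter or colony difference, the culture of this preparation, or an interferon response started by Cre-positive cells and spread to their neighbours may each stand behind it, and none was tested. With 1 library per genotype they are confounded with genotype.

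Beta-like cells of the Cre-negative library stood apart from the other 3 libraries, with 1470 genes at least 1.5-fold different from control offspring. The tables argue against cells of mixed hormone content (1368 genes without them). Marked doublets had been removed beforehand, while unmarked doublets without another hormone stay open. Thinned cells gave 1527 genes, but thinning keeps each cell's expected proportions and mainly changes the weight of deep cells. It therefore cannot decide on depth. A difference of the whole library could account for part of it. Genes past the rule in beta-like cells were followed in endothelial-like cells, keeping those with a higher level there than in beta-like cells. Those higher and those lower in beta-like cells lay 1.07 apart there on the log2 scale (medians 0.695 over 46 and -0.373 over 462 genes). Without that limit on level they lay 1.10 apart. The median of all endothelial-like genes was -0.20, so the 462 lower genes lay closer to it than the 46 higher ones. Only control offspring and Cre-negative cells were compared in this test. Cluster 15 held 90.8% of Cre-negative, 66.1% of IHG and 3.47% of control offspring endothelial-like cells. Cluster 8 held 94.5%, 64.8% and 5.73% of delta-like cells in that order. In alpha-like cells cluster 11 held 82.7% of Cre-negative cells, while cluster 9 held 55.0% of IHG ones. The Cre-negative library was therefore not apart from IHG offspring in every class. Strain background, age of the colony and day of preparation stay open and untested. Much of the difference between Cre-positive and Cre-negative cells may therefore belong to the Cre-negative library rather than to Tet2 and Tet3.

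Immediate early and heat shock genes were lower in the IHG offspring library, though in beta-like cells (median -0.299) not within the shared cluster (0.392) or with each library clustered on its own (0.0157). Thinned alpha-like cells gave -1.17 rather than -1.23, which cannot decide on depth, because thinning keeps each cell's expected proportions. The tables argue against an effect on beta-like cells alone, since the median closest to 0 among alpha-, delta- and endothelial-like cells was -0.840. All 8 of the heat- and dissociation-induced genes tested (Hspa1a, Hspa1b, Hspa8, Hsph1, Dnajb1, Fos, Jun and Egr1) were lower in each of these classes, the result that a difference in islet dissociation and handling between the preparations would give. It cannot be told apart from an effect of the exposure on all islet cells, because each group was 1 preparation. Nor can the share of cells in each cluster alone be told apart, since within the cluster shared most the median was -0.468 in alpha-like, 0.067 in delta-like and -0.305 in endothelial-like cells, between the values set for and against it.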

How the results depend on the processing

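The settings with another reference library, with the most shared cluster, without the interferon-led cluster, without insulin-rich alpha- and delta-like cells, with shared clusters of other classes and with hormone-free CPM in alpha- and delta-like cells were chosen after the results had been seen, while the test on cluster shares was written down beforehand but run after the counts in the shared cluster were known, and its written prediction had been taken out for a time and put back. No paired analysis was possible because each group had 1 library and no label links libraries. Where no reason is given below, the cause was not tested.

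With no doublets removed the gap between the reference libraries (median absolute log2 ratio, 0.343 as reported) was 0.347, and with stricter cell limits 0.358. With median-of-ratios scaling 709 genes were higher and 673 lower with Cre (445 and 1285 as reported), 24 were lower with IHG (39 as reported), and the gap was 0.240; this scaling centres the genes near 0 by construction (median of all genes -0.02 rather than -0.22 with Cre). Without hormone and mitochondrially encoded genes 685 were higher with Cre and 70 with IHG (32 as reported), and the gap was 0.247. The median of nuclear oxidative phosphorylation genes with IHG (-0.012 as reported) became 0.0446 and 0.0494 in these settings.

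With the mean of the cells' own CPM the correlation of the comparisons (-0.112 as reported) was -0.0814, oxidative phosphorylation genes gave -0.0049 with Cre (0.012 as reported) and 0.0420 with IHG, and glucose sensing genes -0.0226 with IHG (0.018 as reported). In thinned cells the beta-like share differed by -27.4 points with Cre (-29.2 as reported) and oxidative phosphorylation genes gave -0.0298 with Cre and 0.0279 with IHG. All of these list medians lay within 0.05 of 0.

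At resolution 0.5 the beta-like share differed by -27.5 points with Cre. At resolution 2 it differed by -12.2 with Cre and -16.8 with IHG (-18.7 as reported), the correlation was 0.0381, the gap 0.291 and Gpx3 with Cre 0.103 higher (log2). With each library clustered on its own the shares differed by -11.0 and -9.49, the correlation was 0.0835 and the gap 0.290, and with IHG the immediate early list gave 0.0157 (-0.299 as reported) and Atf3 0.0121. Without cells of mixed hormone content the gap was 0.328 and Sst with Cre 0.0243.

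At a minimum of 5 CPM 807 genes were higher and 2194 lower with Cre and 88 and 108 with IHG, with a correlation of -0.137 and a gap of 0.356. At 100 CPM these were 127, 255, 9, 12, -0.195 and 0.306. With no minimum and a pseudocount of 1 CPM they were 1080, 2556, 125, 121, -0.0663 and 0.205.

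With the other reference library 124 genes were lower in Cre-positive cells than in control offspring, and 228 were higher and 1505 lower in IHG offspring than in Cre-negative cells. For Cre the shared cluster held only 178 Cre-negative and 334 Cre-positive cells. Within the shared cluster 62 genes were higher with IHG and the correlation was 0.294. There the list of genes kept low in beta cells gave 0.148 with Cre, and glucose sensing genes -0.0936 and immediate early genes 0.392 with IHG. Single genes with Cre were Igfbp5 -0.654, Fev 0.0122, Fabp5 2.18, Dclk1 0.0122, Anpep -1.01, Prss23 0.767, Gpx3 0.298, Basp1 0.597, Sst 0.154 and Msln -0.370, of which Fev, Fabp5, Dclk1, Prss23 and Basp1 rested on 7 to 14 UMIs in both libraries together. With IHG they were Rgs4 0.0635, Atf3 0.235, Ret -0.271, Fosb 0.165, Hmox1 0.0912, Fasn -0.1002, Msln -0.376 and Dusp1 0.0563. Clusters were themselves drawn from expression, so cells of a shared cluster were picked to be alike.

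Without delta-like cells over 3% insulin UMIs the unfolded protein response median with Cre was -0.0728 (0.083 as reported) and that of imprinted genes 0.113 (-0.001), and with IHG that of genes kept low in beta cells was -0.306 (0.217). Without the interferon-led cluster the interferon median of endothelial-like cells with Cre was -0.477 (0.848 as reported); that cluster was picked by these genes and held almost only Cre-positive cells. Within the delta-like cluster shared most the immediate early median with IHG was 0.0666 (-1.0 as reported). For Cre this setting was not run, since each shared cluster of alpha-, delta- and endothelial-like cells held under 100 cells of a library. Without hormone and mitochondrially encoded genes, list medians with Cre in alpha-like cells became 0.172 for beta-cell transcription factors and identity (-0.161 as reported), 0.152 for unfolded protein response (-0.182), 0.104 for antioxidant (-0.230), 0.0681 for imprinted (-0.265) and 0.214 for ribosomal protein genes (-0.120), and in delta-like cells -0.000613 for ribosomal protein genes (0.061).

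Of the 71 genes past the rule with IHG, 25 (35.2%) stayed past it the same way within the shared cluster. This lies between the values set beforehand for and against the share of cells in each cluster as the cause, so whether that share alone gives the difference cannot be told apart from a difference inside the cluster.

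Of the values of named genes under the choices fixed beforehand, 2130 stayed within their counting interval, 701 moved beyond it and 3 changed sign. The other CPM minimums change which genes are counted but not a gene's ratio. Values of named genes under them could not move, and are among those that stayed. Of the list medians 357 stayed, 181 moved and 8 changed sign. Among named genes past the 1.5-fold rule, 90 of 102 with Cre and 26 of 44 with IHG stayed past it under all 13 of these choices. The other CPM minimums, which are among the 13, could not take a gene's ratio below 1.5-fold and so did not test this.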

Other observations

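No test was run for the observations below, and all of them were chosen after the values had been seen.

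Proliferating cells made up 2.16% (1.93 to 2.41) of control offspring and 2.10% (1.84 to 2.38) of IHG offspring cells, against 0.774% (0.561 to 1.04) of Cre-negative and 0.371% (0.259 to 0.516) of Cre-positive cells. With each library clustered on its own these shares were 0.394%, 0.772%, 0.576% and 0%, so the gap between the pairs of libraries depended on clustering them together. Between IHG and control offspring, 431 of 6014 genes were higher and 230 lower in this class. All mice were 8 weeks old, so age in weeks does not separate the pairs of libraries.

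Pancreatic polypeptide-like cells made up 8.60% of Cre-negative, 5.07% of Cre-positive, 1.22% of control offspring and 2.61% of IHG offspring cells. The Cre-positive share was 7.05% with no doublets removed, 7.80% with stricter cell limits and 0% with that library clustered on its own. Ppy in beta-like cells was 4.23-fold higher in IHG than in control offspring, in the direction of these shares. It was also higher in endothelial-like cells (223 against 67.9 CPM), so free RNA may give part of this. Only 33.3% of IHG and 18.2% of control beta-like cells held a Ppy UMI, with 17205 Ppy UMIs over 5891 IHG cells. Over 1% of UMIs came from Gcg, Sst, Ppy and Pyy in 4.63% and 2.20% of beta-like cells. Ppy was thus unevenly spread, and Ppy-rich beta-like cells may give another part. Of 6470 genes in pancreatic polypeptide-like cells 328 were higher and 984 lower in IHG offspring, on 298 against 179 cells. Of these genes 26 and 201 had an interval wholly beyond 1.5-fold. Cluster 17 held 96.6% of the control and 30.9% of the IHG cells of this class, and 17.3% and 2.68% of them had over 3% insulin UMIs.

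Tet1, which was not floxed, stood at 21.3 CPM in Cre-negative beta-like cells and at 9.46, 9.84 and 9.79 CPM in Cre-positive, control offspring and IHG offspring cells. Tet2 stood at 46.7, 33.1, 40.3 and 32.5 CPM in the same order. Outside the Pdx1 lineage, Tet2 was 2.07-fold lower (1.20 to 3.43) in Cre-positive than in Cre-negative endothelial-like cells (73 and 20 UMIs), and 1.06-fold lower with an interval that held 1 (0.577 to 1.81) in macrophage-like cells (138 and 15 UMIs).

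Alpha-like cells of IHG offspring had Gpx4 and Pgls among their highest ratios and glycolysis and antioxidant lists near the top of random lists (medians 0.09 and 0.11, percentiles 99.5 and 99.8), while lipid metabolism genes had 11 of 29 members lower (median -0.29, percentile 0.185). Without hormone and mitochondrially encoded genes these 3 medians were 0.21, 0.23 and -0.17. Without alpha-like cells over 3% insulin UMIs they were 0.12, 0.20 and -0.24. Delta-like cells of Cre-positive mice had 7 of 25 members of the beta-cell transcription factor and identity list higher and 0 lower (median 0.22, percentile 99.97), and a median of 0.26 without cells holding over 3% insulin UMIs. Cluster 6 held 97.6% of these Cre-positive cells and scored 2.27 for delta and 1.26 for beta. Ins2 stood at 53706 CPM in Cre-positive and 8945 CPM in Cre-negative delta-like cells. Beta-cell RNA therefore cannot be told apart from a difference of delta-like cells.

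Beta-like cells of Cre-positive mice set against those of control offspring had lower lipid metabolism (median -0.13, percentile 0.060) and proinsulin processing lists (median -0.13, percentile 0.010), neither of which lay outside the central 95% of random lists against Cre-negative cells. Genes kept low in beta cells had a median of 0.14 in that comparison, against -1.35 with the Cre-negative library as reference.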
